A study of Mus musculus with 6 samples.

How the data were processed

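Primary chondrocytes cultured from mouse articular cartilage were transfected with a control siRNA or with an siRNA against Irf1, and total RNA was taken 36 h later, per the labels' protocols. The series holds 6 RNA-seq libraries, 3 of each treatment, made with a stranded kit that selects polyadenylated RNA, per the labels' protocols. The labels do not state that the replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

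The authors deposited 1 table of raw read counts per library, with a gene symbol joined to an Ensembl gene identifier and 1 column of whole-number counts that are not normalised. Reads were trimmed with Trimmomatic 0.39, checked with FastQC and aligned with STAR, and the genome build was GRCm39 (mm39), per the submitters' processing notes. The versions of FastQC and STAR, the counting tool, the annotation release and the strand setting of the counting are not given in the sources used here. Antisense and overlapping genes can therefore share reads. So can near-identical genes, among them the class I genes of the H2-Q, H2-T and H2-M regions, guanylate-binding proteins, glutathione S-transferases of the Gsta group, Psme2, Fth1, Ftl1, Bcl2a1 and the ribosomal protein genes with their many pseudogenes, and their values are uncertain to that extent. The table lists 55377 genes, no row stands for anything but a gene, and 79 symbols belong to more than 1 identifier.

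Total counts ranged from 22349142 to 29282494 per library. Library pairs of the same group differed by more than counting noise (chi-square over degrees of freedom of 5.8 to 16.7 across genes), so no library was a copy of another.

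Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group as the factor, which left 14683 genes holding over 99.9% of the counts of each library. Libraries were scaled with TMM factors, and each gene was tested with the quasi-likelihood F test (glmQLFit with the robust option, glmQLFTest; two-sided) for Irf1 siRNA against control siRNA, with the group as the only term. Adjusted p-values follow Benjamini and Hochberg over all tested genes, and a gene counts as changed below 0.05. Every adjusted p of a gene comes from this test unless another is named. Standard errors of log2 fold changes were taken as the absolute log2 fold change divided by the square root of the F statistic. Levels are TMM-normalised CPM, counts scaled to a fixed library total, given as mean ± SD with n = 3. Gene lists were tested with camera from limma 3.58.1 at an inter-gene correlation of 0.01, adjusted over the 29 lists with more than 1 tested member, and again with the correlation estimated for each list. The exact permutation test of 1 value in a design of 3 against 3 cannot give p below 0.1, so single values were tested only within the model across genes.

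Before the data were examined, 31 gene lists were fixed, 9 of them as main lists: type I interferon-stimulated genes, interferon-gamma and IRF1 target genes, MHC class I antigen presentation, DNA double-strand break repair, single-strand, mismatch and excision repair, p53 targets, cell cycle and mitosis, cartilage matrix, and cartilage catabolism. The other lists cover chondrocyte hypertrophy, senescence-associated secretion, NF-kB targets, interferon signalling, replication-dependent histones, apoptosis, TGF-beta and BMP response, Wnt, hypoxia, the unfolded protein response, NRF2 targets, cholesterol and fatty acid synthesis, immediate early genes, ribosomal proteins, mitochondrially encoded genes, and markers of osteoblasts, fibroblasts, macrophages, osteoclasts, endothelial and mural cells, skeletal muscle, and erythroid and neutrophil cells. The rule for named genes was fixed at the same time. It takes Irf1 and its family, then the 10 largest rises and the 10 largest falls among changed genes with a mean of at least 5 CPM, no overlap between the groups and a symbol that is not a clone or predicted name, then up to 4 changed members of each list with the smallest adjusted p. Members named beyond this rule, where a count of 5 or fewer is spelled out, were chosen after their values were seen. A few genes that the rule names are not reported here.

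Sequence features came from GENCODE mouse release M21, which describes GRCm38 and not the authors' build. It was used by gene identifier only, for transcript and untranslated region sequences and for GC content and length. Of the 14683 tested genes, 14653 (99.8%) had a matching identifier. After the data were seen, every 7-base word was scored in the 3′ untranslated regions (3′ UTRs) of 10083 genes with a mean of at least 5 CPM and a 3′ UTR of at least 50 bases. The score is a z value from a regression of the log2 fold change, limited to 2 in either direction, on the presence of the word, the length of the 3′ UTR and its GC content. Of these words, 16192 were present in at least 50 genes. Chance was judged from 100 permutations of the fold changes over genes, and every 19-base window of the Irf1 transcript was then read as a possible siRNA duplex.

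The edgeR test, camera and the word score were tested on simulated data. In counts simulated for this comparison with 200 changed genes among 14536 tested, the edgeR test recovered 24% of 1.2-fold changes, 82% of 1.5-fold changes, 96% of 2-fold changes and 100% of 4-fold changes, 50 genes each. False calls made up 7.93% of all calls, 13 genes, which is above the nominal share. A simulated list of 40 genes lowered 1.2-fold was called by camera and 0 of 20 random lists were. Genes were simulated independently of each other, so this does not check camera on lists whose members move together. A word planted in the 3′ UTRs ranked 1 in the word score.

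Alternatives were DESeq2 size factors, upper-quartile scaling, the DESeq2 1.42.0 Wald test, limma-voom, no filter or a stricter filter on low counts (5 CPM in 3 libraries), an adjusted p under 0.01, a fold of at least 1.5, the replicate number as a block, counts thinned to the smallest library, and each library left out in turn. For the lists, fry (which tests a list against no change and not against other genes), rank-based camera and leaving out Irf1 were added. A correction for GC content and length (loess with a span of 0.4 per library), the same with the replicate block, the removal of genes carrying a seed site or having no annotated 3′ UTR of at least 50 bases, and the removal of the latter alone were chosen after the data were seen.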

Results

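Chondrocytes, the cells that make and keep cartilage matrix, were grown in primary culture from mouse articular cartilage and profiled by RNA-seq 36 h after transfection with a control siRNA or an siRNA against Irf1. Irf1 encodes interferon regulatory factor 1, a transcription factor that interferons induce. The design was 3 control siRNA libraries against 3 Irf1 siRNA libraries. The control libraries held 28731426, 28565096 and 29282494 counts, and the Irf1 siRNA libraries held 22349142, 26752065 and 23387622, so every knockdown library was shallower than every control library. Between 20990 and 21643 genes had at least 1 count. Col2a1, the collagen that marks chondrocytes, took the largest share of counts in each library, from 6.09% to 8.15%. The first principal component of log2 CPM carried 50.3% of the variance and separated the treatments, and the second carried 16.9%. Libraries of the same treatment correlated at 0.993 to 0.9944 across genes and libraries of different treatments at 0.9855 to 0.9891, where genes are not independent replicates. The common biological coefficient of variation was 6.44%.

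The target gene was measured first, since it checks the labels. Irf1 (ENSMUSG00000018899.18) had 312, 355 and 362 counts in the control libraries and 125, 140 and 141 in the Irf1 siRNA libraries. Its level was 11.98 ± 0.759 CPM with control siRNA and 5.58 ± 0.471 CPM with Irf1 siRNA (SD, n = 3), which left 46.5% of the transcript. The fall of 2.15-fold (log2 fold change −1.10, SE 0.11) had an adjusted p of 3.0e-06 in the edgeR quasi-likelihood test, and all 6 libraries lay on the side their label gives. No other family member reported here passed the threshold. Irf2 gave a log2 fold change of 0.02 (adjusted p = 0.923), Irf3 −0.04 (0.727), Irf5 0.58 (0.169), Irf7 0.05 (0.902) and Irf9 −0.15 (0.321). Irf4, with 3 counts over the control libraries and 4 over the knockdown libraries, and Irf8, with 7 and 8, were too low to test.

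**Figure D1:**
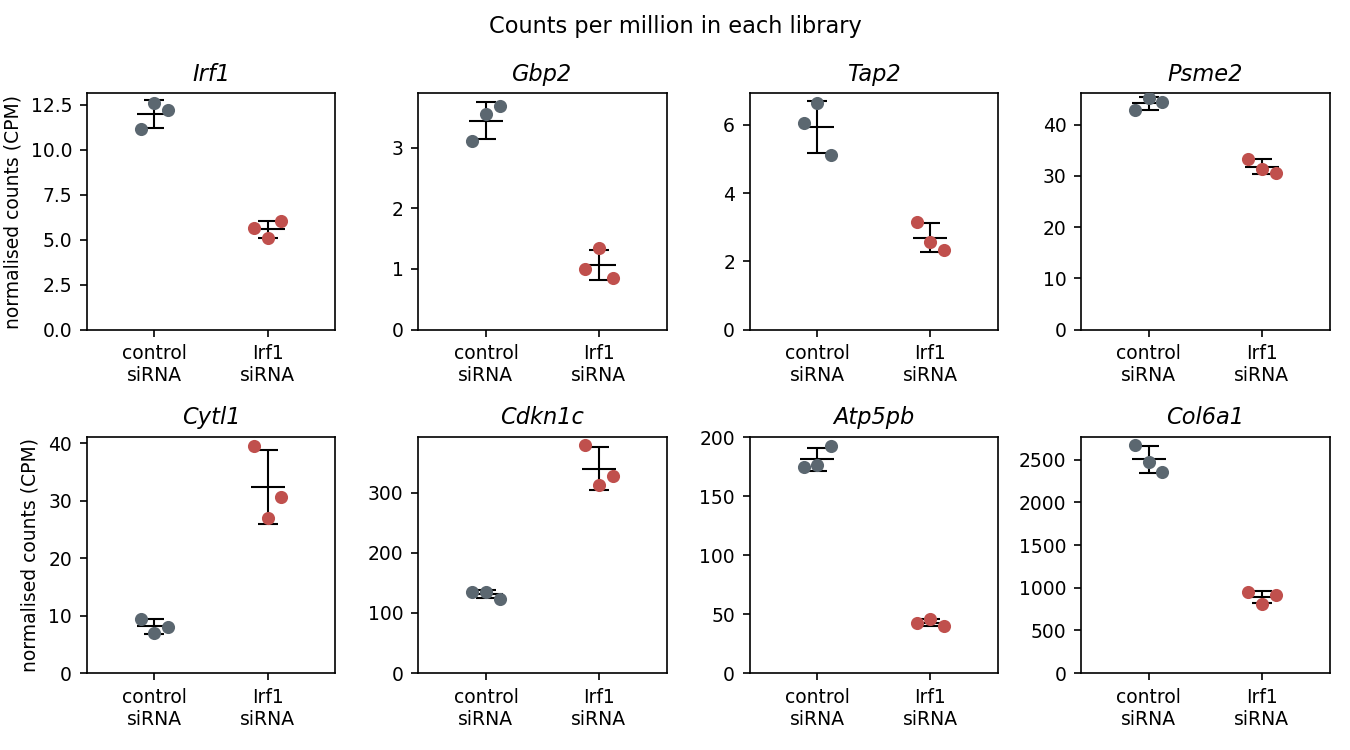
TMM-normalised CPM of 8 genes in each library, with control siRNA in grey and Irf1 siRNA in red; points are libraries, the wide bar is the mean and the whiskers are the SD (n = 3). Irf1 fell from 11.98 to 5.58 CPM, Gbp2, Tap2, Psme2, Atp5pb and Col6a1 were lower in every Irf1 siRNA library than in any control library, and Cytl1 and Cdkn1c were higher.

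With Irf1 siRNA, 3289 of 14683 tested genes (22.4%) differed at an adjusted p under 0.05 in edgeR, 1522 higher and 1767 lower. Most of these changes were small: the median changed gene differed by 1.29-fold. A fold of at least 1.5 was reached by 385 higher and 430 lower genes, and a fold of at least 2 by 158 and 121. The groups did not overlap for 5601 genes (38.1%), against 10% by chance for 3 against 3. The count of higher genes depended most on single libraries, with 980 without control replicate 2 and 959 without Irf1 siRNA replicate 3.

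Among genes with a mean of at least 5 CPM, the largest rise was that of Cytl1 (ENSMUSG00000062329.5), a secreted protein of chondrocytes, from 8.13 ± 1.24 to 32.4 ± 6.42 CPM (SD, n = 3; log2 fold change 1.99, SE 0.15, adjusted p = 4.6e-06). Grem1 (ENSMUSG00000074934.4), a BMP antagonist, rose 3.02-fold and Cdkn1c (ENSMUSG00000037664.14), which encodes the cyclin-dependent kinase inhibitor p57, rose 2.60-fold from 130.8 ± 6.64 to 339.9 ± 35.1 CPM (adjusted p = 4.9e-09). The other large rises were those of the receptor gene Gprc5b (1.41 on the log2 scale), Rnf227 (1.35), the glutathione transferase genes Gsta4 (1.35) and Gsta1 (1.30), the cytokine gene Il17d (1.33), the aldehyde dehydrogenase gene Aldh3a1 (1.29) and the water channel gene Aqp5 (1.23). The largest fall was that of Atp5pb (ENSMUSG00000000563.18), a subunit of mitochondrial ATP synthase, from 181.1 ± 9.88 to 42.6 ± 2.95 CPM (log2 fold change −2.09, SE 0.07, adjusted p = 3.3e-11). Cnn1 (ENSMUSG00000001349.6) and Actg2 (ENSMUSG00000059430.15), a calponin and an actin of smooth muscle, fell by 1.94 and 1.62 on the log2 scale. Mmgt1 fell by 1.92, the LIM protein gene Csrp1 by 1.88, Cmtm6 by 1.78, Serpinb9, which encodes a granzyme B inhibitor, by 1.44, and Ppib, which encodes cyclophilin B, by 1.43 on the log2 scale. The calponin gene Cnn2 was 2.82-fold lower. Col6a1, a chain of type VI collagen, went from 2503 ± 160.0 to 891.4 ± 69.9 CPM, a 2.81-fold fall (adjusted p = 1.6e-09).

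Irf1 itself was not among the strongest changes. It ranked 143 by p-value, and 35 lower genes with a mean of at least 5 CPM fell by more than it did. These falls went with short words in the 3′ UTR: ACTGATC or CTGATCA, and GCTATCT or CTATCTA, were present in 8 of the 10 named largest falls (all but Cnn1 and Actg2) and in 1 of the 10 largest rises (Grem1). Of all lower genes with an annotated 3′ UTR, 744 of 1699 (43.8%) held at least 1 of these words. This compares with 1963 of 9652 genes not past the threshold (20.3%) and 200 of 1405 higher genes (14.2%). The words had been chosen for going with falls in these same genes, so the shares describe that choice and are not a separate test. They are not adjusted for the length of the 3′ UTR. Among the 65 lower genes named by the rule, 34 hold such a word in the 3′ UTR; outside the 8 above they include Cmpk2, Dtx3l, Irgm2, Gen1, Rnf168, Blm, Ercc4, Rrm2b, Zmat3, Tigar, Rrm2, Gins2, Hapln1, Epas1, Alpl, Stat3, Cflar, Sfrp1, Fzd1, Bnip3, Car12, Scd1, Itgb3 and Nfatc1. A word only in the coding sequence was present in Irf1 itself, Gbp2, Samd9l, Mdc1, Lig3, Acta2, Col3a1, Tnc and Hyou1. Genes with an annotated 3′ UTR and no word in either region, 7897 of those tested, gave 1643 changed genes when p-values were adjusted over them alone. Of these, 62.4% were higher. The fit and the scaling were still those of all genes, so this share follows in part from leaving out words that went with falls. The setting without genes holding a word, given for the lists below, also leaves out genes with no annotated 3′ UTR.

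**Figure D2:**
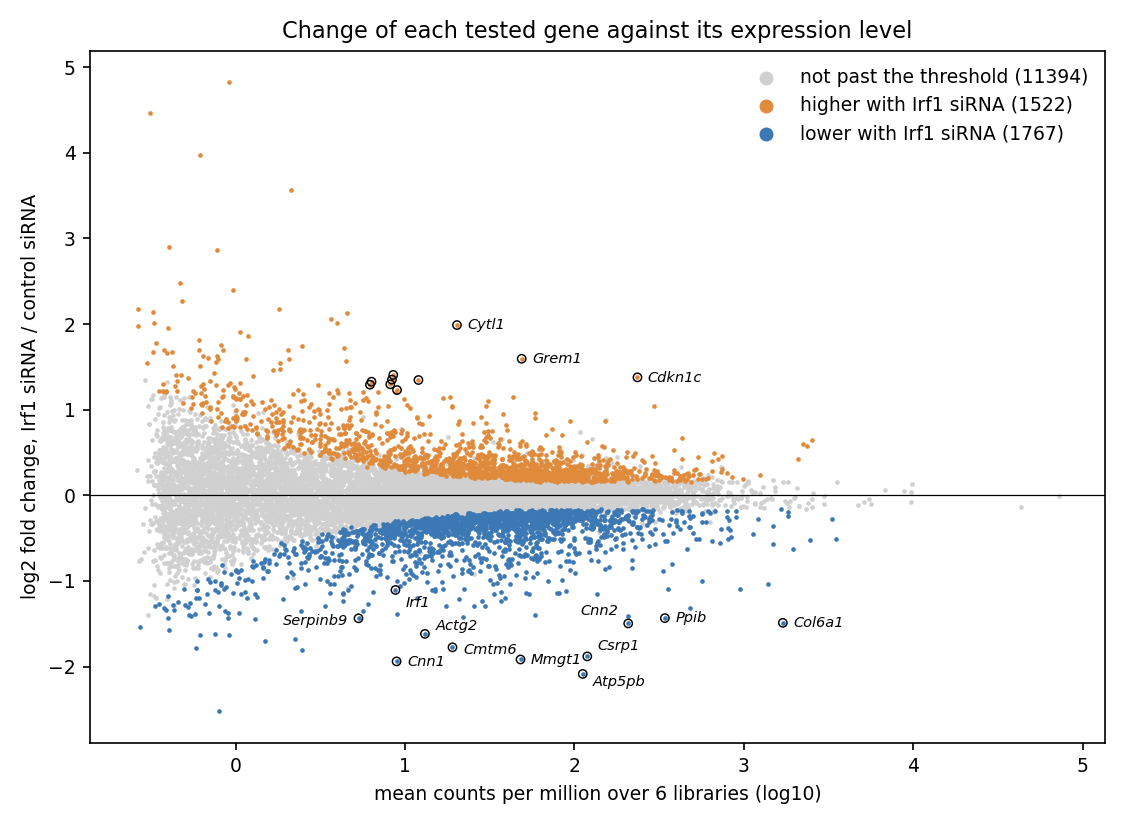
Log2 fold change of each tested gene (Irf1 siRNA over control siRNA) against its mean level over the 6 libraries in CPM on a log10 scale; orange genes were higher and blue genes lower at an adjusted p under 0.05 in edgeR. Circles mark Irf1 and the 10 largest rises and 10 largest falls named by the rule, with names left off where rises lie close together. Genes such as Atp5pb, Csrp1 and Col6a1 fell further than Irf1.

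The first set of comparisons asked whether genes under interferon control changed with Irf1 siRNA. Of 21 tested genes of MHC class I antigen presentation, 8 fell and 0 rose (8 and 0 adjusted over the list alone). Tap2, a subunit of the transporter that carries peptides into the endoplasmic reticulum, fell from 5.94 ± 0.757 to 2.70 ± 0.418 CPM (log2 fold change −1.14, SE 0.16, adjusted p = 8.5e-05). The proteasome activator gene Psme2 fell by 0.47 on the log2 scale (SE 0.06, adjusted p = 7.4e-05), the class I gene H2-Q4 by 0.70 (SE 0.11, adjusted p = 2.5e-04) and Tapbp, which encodes tapasin, by 0.34 (SE 0.06, adjusted p = 8.2e-04). The list lay below other genes in camera (adjusted p = 0.0016, and 0.70 with an estimated correlation). A word in the 3′ UTR was found in 1 of its 8 lower genes, of which Psme2 had no annotated 3′ UTR to search. With the coding sequence also counted, 14 of the 20 members searched held no word, and 5 of these were lower when adjusted over the genes left.

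Of 18 tested interferon-gamma and IRF1 target genes, 5 fell and 1 rose (8 and 1 adjusted over the list alone). Gbp2, a guanylate-binding protein gene, fell from 3.44 ± 0.302 to 1.06 ± 0.252 CPM (log2 fold change −1.67, SE 0.20, adjusted p = 2.6e-05), and the complement gene C1s1 fell by 0.54 on the log2 scale (adjusted p = 0.0102). Gbp7 fell by 1.38, Irgm2 by 1.16 and Cd274, which encodes PD-L1, by 1.10, whereas the chemokine gene Cxcl10 rose by 0.59 with an adjusted p of 0.049. The call of Gbp7 was lost without Irf1 siRNA replicate 1 (adjusted p = 0.0536) and that of Irgm2 without control replicate 2 (0.0955) or Irf1 siRNA replicate 3 (0.0627). The list was lower in camera (adjusted p = 0.040; adjusted p = 0.70 with an estimated correlation). That call was also lost without control replicate 2 (0.081), without Irf1 siRNA replicate 2 (0.17). After a GC and length correction (0.077) the mean log2 fold change was −0.39 against −0.40 before, and without genes holding a word (0.14) it was −0.22 over 13 members. Leaving out only genes with no annotated 3′ UTR, which removed no member, also ended the call (0.067).

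Type I interferon-stimulated genes as a list were not past the threshold in camera. Of 31 tested, 7 fell and 1 rose (8 and 1 adjusted over the list alone), with a camera adjusted p of 0.17. The fry test, which sets a list against no change and not against other genes, gave 0.048. Samd9l fell by 1.04 on the log2 scale (SE 0.15, adjusted p = 1.6e-04), and Parp9 and Dtx3l, which encode partners in 1 ubiquitin ligase complex, fell by 0.58 (adjusted p = 0.00138) and 0.70 (adjusted p = 0.00887). Oasl1 rose by 1.30 with an adjusted p of 0.049. Cmpk2 fell by 1.26 (adjusted p = 0.0228), a call lost with DESeq2 (0.0666) and without any single library but control replicate 3 (0.0565 to 0.0995). Of 29 tested genes of interferon regulatory factors and interferon signalling, 3 fell (Irf1, Stat3 and Irf2bpl) and 2 rose (Jak2 and Cgas), the same counts adjusted over the list alone, with a camera adjusted p of 0.93. Stat3 fell by 0.63 on the log2 scale (SE 0.06, adjusted p = 1.2e-06). Irf2bpl (adjusted p = 0.0297) lost its call without control replicate 1 or 2 or Irf1 siRNA replicate 2 or 3 (0.054 to 0.119), with DESeq2 (0.0519) and with upper-quartile scaling (0.0524). Jak2 (adjusted p = 0.0351) lost it without the same libraries (0.0698 to 0.166) and with no filter (0.0761).

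Genes of DNA repair, which were among the main lists, were tested as well. Of 47 tested genes of DNA double-strand break repair, 12 fell and 0 rose (13 and 0 adjusted over the list alone), with a mean log2 fold change of −0.15. Gen1, which encodes a Holliday junction resolvase, fell from 15.5 ± 0.883 to 10.6 ± 0.541 CPM (log2 fold change −0.54, SE 0.09, adjusted p = 4.1e-04). The helicase gene Blm fell by 0.35 (SE 0.08, adjusted p = 0.0054), the ubiquitin ligase gene Rnf168 by 0.32 (SE 0.07, adjusted p = 0.00404) and Mdc1, a mediator of the damage checkpoint, by 0.26 on the log2 scale (SE 0.07, adjusted p = 0.00923). The list was lower in camera (adjusted p = 0.017; adjusted p = 0.74 with an estimated correlation). Words in the 3′ UTR were present in 5 of the 12 lower genes and 13 of the 47 tested. With the coding sequence also counted, 24 of the 47 held no word, and 5 of these were lower when adjusted over the genes left. Of the genes named here, Gen1, Blm and Rnf168 held a word in the 3′ UTR and Mdc1 in the coding sequence. The call was lost without genes holding a word (camera adjusted p = 0.054) and without control replicate 3 (0.073).

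Genes of single-strand, mismatch and excision repair were not past the threshold as a list (47 tested, 5 lower and 2 higher; 4 and 2 adjusted over the list alone; camera adjusted p = 0.97). Ercc4 fell by 0.37 and Lig3 by 0.24 on the log2 scale, with adjusted p of 0.00503 and 0.00615, Ercc3, Parp2 and Mgmt also fell, and Gtf2h1, a subunit of TFIIH, rose by 0.31 (adjusted p = 0.00147). Ercc1 rose by 0.24 (adjusted p = 0.0231), a call lost without control replicate 1 or 3 or Irf1 siRNA replicate 1 or 3 (0.0697 to 0.113). Among 40 tested p53 target genes, 9 fell and 5 rose, the same counts adjusted over the list alone, and camera gave an adjusted p of 0.71. Rrm2b, which supplies deoxynucleotides for repair, fell by 0.79 (SE 0.11, adjusted p = 8.5e-05), Tigar by 0.58 (SE 0.12, adjusted p = 0.00205) and Zmat3 by 0.33 (SE 0.06, adjusted p = 0.00135). Cdip1 rose by 0.46 (SE 0.07, adjusted p = 3.9e-04), as did Trp53inp1, Sulf2, Btg2 and Rap2b. Cdkn1a, the p53 target that arrests the cell cycle, gave a log2 fold change of 0.06 (adjusted p = 0.536).

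Genes of cell division were tested next. Of 46 tested cell cycle and mitosis genes, 23 fell and 1 rose (28 and 1 adjusted over the list alone). The proliferation marker Mki67 fell from 73.0 ± 1.58 to 55.6 ± 2.25 CPM (log2 fold change −0.39, SE 0.06, adjusted p = 1.6e-04). Rrm2, a ribonucleotide reductase subunit gene of S phase, fell by 0.46 (SE 0.06, adjusted p = 9.6e-05), the replication gene Gins2 by 0.64 on the log2 scale (SE 0.09, adjusted p = 1.2e-04), and Ccne1, which encodes cyclin E1, rose by 0.45 (SE 0.07, adjusted p = 2.5e-04). The list was lower in camera (adjusted p = 3.4e-06, and 0.70 with an estimated correlation), with a word in the 3′ UTR of 3 of the 23 lower genes. With the coding sequence also counted, 31 of the 46 held no word, and 15 of these were lower when adjusted over the genes left. None of 13 tested replication-dependent histone genes changed in edgeR, 0 adjusted over the list alone (camera adjusted p = 0.70), in libraries of polyadenylated RNA.

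Individual cartilage genes changed, and their lists were not past the threshold in camera. Of 32 tested cartilage matrix and chondrocyte genes, 6 rose and 4 fell, the same counts adjusted over the list alone (camera adjusted p = 0.92). Hapln1, which encodes the link protein of aggrecan and hyaluronan, fell from 1877 ± 36.7 to 915.1 ± 59.7 CPM (log2 fold change −1.04, SE 0.06, adjusted p = 1.6e-08), and Clec3a, Chad and Fmod also fell. Besides Cytl1, rises were seen in Prg4, which encodes lubricin, by 0.46 (SE 0.08, adjusted p = 0.00112) and Itm2a by 0.45 (SE 0.07, adjusted p = 2.3e-04). The main matrix genes gave log2 fold changes of −0.01 for Col2a1 (adjusted p = 0.968) and 0.05 for Acan (adjusted p = 0.784), and their regulator Sox9 gave 0.09 (adjusted p = 0.342). Of 28 tested catabolic enzymes and mediators, 5 rose and 4 fell, again the same adjusted over the list alone (camera adjusted p = 0.74). Epas1, which encodes HIF-2 alpha, fell from 16.3 ± 0.972 to 7.10 ± 0.768 CPM (log2 fold change −1.20, SE 0.10, adjusted p = 6.6e-07), and the aggrecanase gene Adamts5 fell by 0.83 (SE 0.09, adjusted p = 7.4e-06), as did Adamts4 and Mmp2. The inhibitor gene Timp2 rose by 0.43 (SE 0.05, adjusted p = 3.0e-05) and Mmp3, which encodes stromelysin-1, by 0.61 (SE 0.12, adjusted p = 0.00366), followed by Ctsb, Htra3 and Cemip. Mmp13, the main collagenase, gave 0.09 (adjusted p = 0.808). Of 18 tested hypertrophy and mineralisation genes, 4 rose and 3 fell (6 and 4 adjusted over the list alone; camera adjusted p = 0.39). Spp1 rose by 0.60, and Ank and Enpp1, which raise extracellular pyrophosphate, rose by 0.77 and 0.36, with Mgp also higher. Alpl, the phosphatase that removes pyrophosphate, fell by 0.93 (SE 0.09, adjusted p = 1.5e-06), and Col10a1 and Vegfa were lower too.

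Several antioxidant genes rose. Of 30 tested NRF2 target genes, 12 rose and 3 fell (13 and 3 adjusted over the list alone). Gsta4 rose from 6.78 ± 1.19 to 17.2 ± 2.14 CPM (adjusted p = 2.1e-06), Osgin1 rose by 1.21 on the log2 scale (SE 0.14, adjusted p = 1.3e-05) and Fth1, the ferritin heavy chain gene, by 0.57 (SE 0.06, adjusted p = 3.7e-06), while Prdx6, Gstp1 and Gpx3 fell. The list was higher in camera (adjusted p = 1.3e-05; adjusted p = 0.57 with an estimated correlation). Of 49 ribosomal protein genes, 18 rose by small amounts and 0 fell (36 and 0 adjusted over the list alone). Rpl22 rose by 0.31 (SE 0.06, adjusted p = 0.00271) and Rpl26 by 0.26 (SE 0.06, adjusted p = 0.00525). All protein-coding genes whose symbol starts with Rpl or Rps and a digit, a set that differs somewhat from the list, were also summed. They took 2.62% to 2.85% of counts in the control libraries and 3.03% to 3.25% in the shallower Irf1 siRNA libraries. Camera placed the list of 49 above other genes (adjusted p = 1.3e-06, and 0.70 with an estimated correlation), and fry against no change gave 0.061. Of 29 tested immediate early genes, which also respond to handling, 8 rose and 1, Ier3, fell (9 and 2 adjusted over the list alone). Klf4 rose by 0.43 (adjusted p = 0.00147) and Egr1 by 0.45 (adjusted p = 0.00305). The list was higher in camera (adjusted p = 0.0082, and 0.70 with an estimated correlation), while fry against no change gave 0.088. The camera call was lost without genes holding a word (0.085). The mean log2 fold change there was 0.209 ± 0.056 (SE, 20 members) against 0.267 ± 0.056 (29 members), so that loss cannot be put down to words alone.

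**Figure D3:**
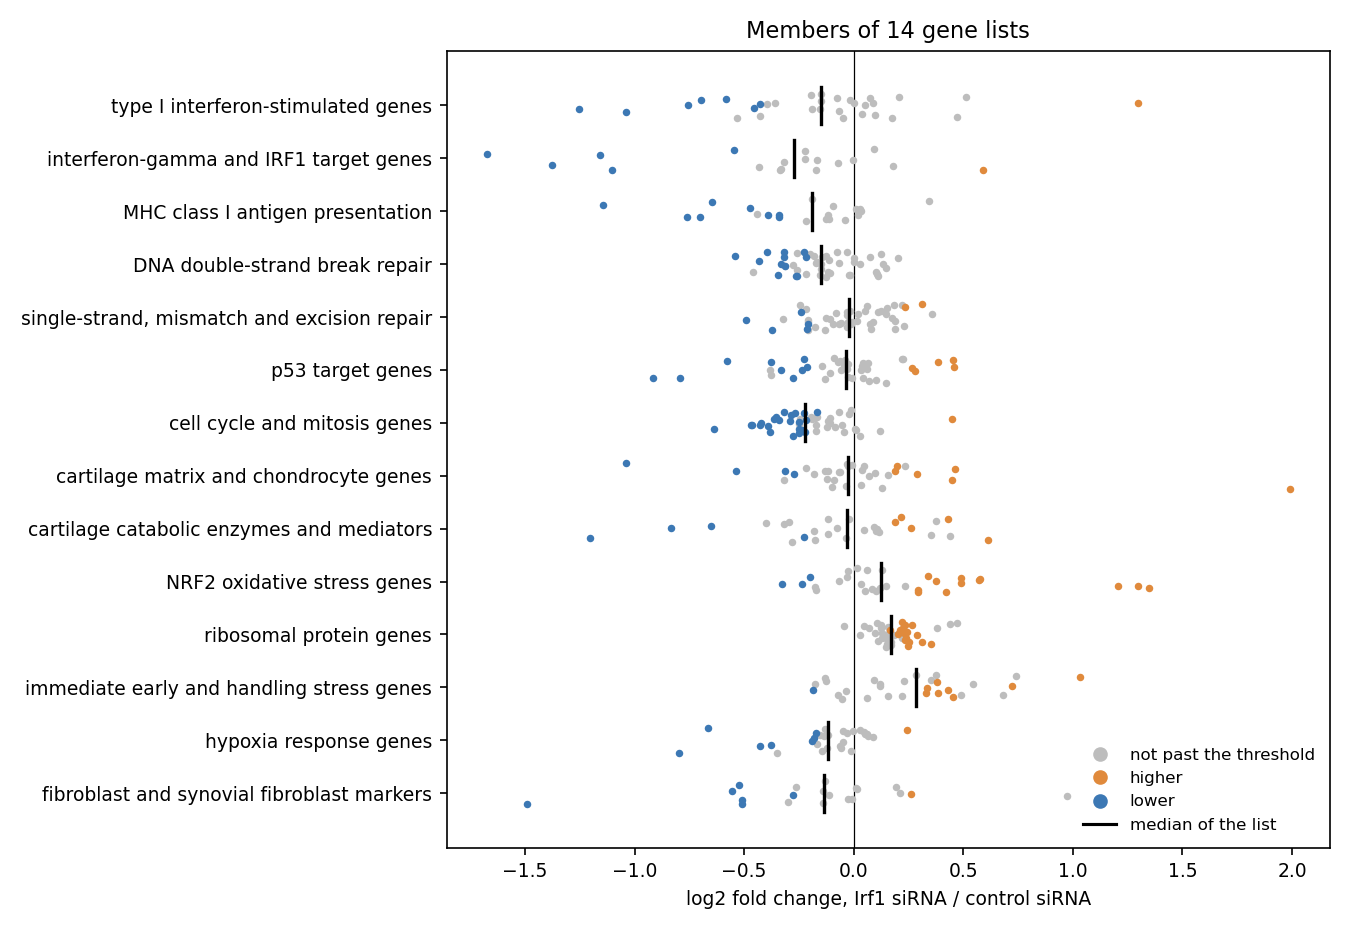
Log2 fold change (Irf1 siRNA over control siRNA) of each tested member of 14 gene lists, 9 of them the main lists; orange members were higher, blue members lower and grey members not past an adjusted p of 0.05 in edgeR, and the vertical bar is the list median. The medians of the NRF2, ribosomal protein and immediate early lists lie above 0, and those of the MHC class I, cell cycle and hypoxia lists below 0.

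Some hypoxia genes fell. Of 29 tested, 7 fell and 1, Plod2, rose (9 and 1 adjusted over the list alone). Bnip3, a mitophagy receptor gene, fell from 479.2 ± 31.2 to 275.4 ± 6.26 CPM (log2 fold change −0.80, SE 0.06, adjusted p = 1.8e-07), the carbonic anhydrase gene Car12 fell by 0.67 (SE 0.06, adjusted p = 1.6e-06) and the adrenomedullin gene Adm by 0.43 (SE 0.06, adjusted p = 1.0e-04). The list was lower in camera (adjusted p = 0.011, and 0.74 with an estimated correlation). A word in the 3′ UTR was held by 3 of its 7 lower genes, among them Bnip3 and Car12. With the coding sequence also counted, 19 of the 29 held no word, and 3 of these were lower when adjusted over the genes left. The call was lost without genes holding a word (0.085) and without Irf1 siRNA replicate 2 (0.071), and fry against no change gave 0.061.

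The remaining pathway lists held changed genes in both directions and none was past the threshold in camera. For TGF-beta and BMP response, 6 of 33 rose and 6 fell, the same adjusted over the list alone (camera adjusted p = 0.70): Bambi rose by 0.47 and Smad4 by 0.37. For the Wnt pathway, 6 of 30 rose and 5 fell (10 and 5 adjusted over the list alone; camera adjusted p = 0.62). Nkd1 rose by 1.21, the secreted antagonist gene Sfrp1 fell by 1.35, and Dkk3, Fzd1, Tcf7l1 and Lef1 also fell. Among 29 senescence-associated secretory genes, 3 rose (Il11, Igfbp4 and Ccl5) and 4 fell (among them Plaur, Cxcl5 and Vegfa), the same adjusted over the list alone (camera adjusted p = 0.90). Of 30 NF-kB targets, 3 rose (Tnfaip2, Tnip1 and Ccl5) and 4 fell (Irf1, Tnfaip3, Bcl3 and Nfkb1), with 3 and 5 adjusted over the list alone (camera adjusted p = 0.74). Ccl5 (adjusted p = 0.0328) lost its call with DESeq2 (0.0649) and without any single library but control replicate 3 (0.0525 to 0.118), and Tnip1 (adjusted p = 0.0187) lost it without control replicate 3 or Irf1 siRNA replicate 1 or 3 (0.0703 to 0.0791). Of 30 apoptosis regulators, 2 rose (Mcl1 and Bcl2l2) and 4 fell (Pmaip1, Cflar, Bak1 and Bax), the same adjusted over the list alone (camera adjusted p = 0.98).

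Among 30 genes of the unfolded protein and integrated stress response, 2 rose (Atf3 and Chac1) and 3 fell (Hyou1, Edem1 and Sel1l), the same adjusted over the list alone (camera adjusted p = 0.98). Of 30 cholesterol and fatty acid synthesis genes, 3 rose (Idi1, Cyp51 and Fdps) and 6 fell (4 and 6 adjusted over the list alone; camera adjusted p = 0.98), with Scd1 among those that fell. The median, the mean and the camera direction differed in sign for the cartilage matrix, senescence, interferon signalling, unfolded protein, cholesterol and macrophage lists, none of which was past the threshold.

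Markers of other cell types were compared as well, since primary cultures can hold cells besides chondrocytes. Of 20 tested fibroblast markers, 6 fell and 1, Prrx1, rose (8 and 1 adjusted over the list alone). Besides Col6a1, Col3a1 fell by 0.55 (SE 0.08, adjusted p = 3.4e-04), Col1a2 by 0.53 (SE 0.08, adjusted p = 1.2e-04) and Tnc by 0.51 (SE 0.07, adjusted p = 9.4e-05). The list was lower in camera (adjusted p = 0.0016; adjusted p = 0.48 with an estimated correlation), a call lost without genes holding a word (0.12) and in rank-based camera (0.060). Osteoblast markers were not past the threshold as a list (13 tested, 3 lower, 0 higher; 4 and 0 adjusted over the list alone; camera adjusted p = 0.084, but 0.048 with fry), with Alpl, Col1a1 and Col1a2 lower. Few macrophage and leukocyte markers were high enough to test: Cd14 and Cd68 rose among 6, 2 higher and 0 lower (3 and 1 adjusted over the list alone; camera adjusted p = 0.70). The rise of Cd68 (adjusted p = 0.0316) was lost without control replicate 2 or any 1 of the Irf1 siRNA libraries (0.057 to 0.15). Of 6 osteoclast markers, Itgb3 and Nfatc1 fell, 2 adjusted over the list alone (camera adjusted p = 0.24, 0.031 with fry), and of 10 endothelial and mural markers Mcam rose by 0.86 and Acta2 fell by 1.31, also 1 each adjusted over the list alone (camera adjusted p = 0.70, 0.031 with fry). Of 5 skeletal muscle markers, Des rose, 1 adjusted over the list alone (camera adjusted p = 0.72), a call (adjusted p = 0.0446) that each left-out library ended (0.0593 to 0.145), as did DESeq2 (0.097) and no filter (0.0786). Lcn2 was the only tested erythroid or neutrophil marker (log2 fold change 0.18, adjusted p = 0.721), with 0 calls adjusted over the list alone. The mitochondrially encoded genes were not analysed here.

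In all, camera called 9 of the 29 lists tested at the preset correlation and 0 with a correlation estimated for each list. At an unadjusted p under 0.05, 5043 genes differed in edgeR.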

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

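The GC and length corrections, alone or with the replicate block, and the analyses without genes holding a word of the siRNA seeds or without genes lacking an annotated 3′ UTR were chosen after the data were seen. Of 2065 comparisons for the 119 named genes, 2017 kept their side of the threshold and 48 (in 12 genes) lost the call. Among comparisons with a call in either fit, 0 reversed. A change of sign in a gene with no call in either fit was not counted. The log2 fold change of Irf1 stayed between −1.17 and −1.02. The count of changed genes was 3289 and became 3314 with DESeq2 size factors, 3401 with upper-quartile scaling (54.5% of them higher, against 46.3%), 2911 with DESeq2, 3269 with limma-voom, 3522 with no filter, 2938 with a stricter one and 3149 after thinning to 22349142 counts per library. In none of these did a gene called in both change sign. Leaving out single libraries gave 2235 to 3114 changed and 959 to 1398 higher genes, with fewer libraries in each test. An adjusted p under 0.01 left 1796 genes (757 higher, 1039 lower) and a fold of at least 1.5 left 815 (385 and 430). Without genes holding a word, 1643 changed and 618 were lower among 7897 tested, fewer by construction. That setting also leaves out genes with no annotated 3′ UTR, and leaving out those alone gave 3215 changed and 1751 lower among 12756.

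With the replicate block the count was 3728, 1744 of them higher, and the osteoblast list passed the threshold (0.0047). Replicates of the same number correlated at 0.2, −0.04 and 0.05 after removal of group means, and 3 of 6 libraries correlated best with their own number, so the values do not show pairing by number, and the libraries were treated as unpaired. The GC and length correction gave 4350 changed genes, 2226 of them higher, and with the block as well 4845 and 2497. The cause was not tested.

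The type I interferon list passed the threshold with no filter (0.024) and with fry (0.048), which tests against no change, and fry also called the osteoblast (0.048), osteoclast and endothelial lists (0.031 each). The interferon-gamma list ranged from 0.024 to 0.17 when single libraries were left out and lost its call with the GC and length correction (0.077; mean −0.39 against −0.40, so the fold stayed), with that correction and the block (0.10) and without genes holding a word (0.14; mean −0.22). It also lost its call when only genes with no annotated 3′ UTR were left out (0.067), with every member kept. The double-strand break repair list ranged from 0.0024 to 0.073 when single libraries were left out and gave 0.054 without genes holding a word, against 0.034 without genes lacking an annotated 3′ UTR. A correlation estimated per list (0.036, 0.195, 0.428 and 0.15, in place of 0.01) ended the calls of the interferon-gamma, MHC class I and cell cycle lists (0.70 each) and of the double-strand break repair list (0.74). That setting also uses the few residual degrees of freedom of the libraries, and it ended the fibroblast call (0.48) at a correlation of −0.002. For this and the other changes the cause was not tested. Low counts limit what could be tested: Irf4 and Irf8 could not be tested, and 18 of 39 interferon-gamma targets could. An unstranded count was not run, since 1 count column was held, and neither was a GC correction with the authors' annotation.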

Other observations

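The search for siRNA seed words and the test of contractile genes were chosen after the results were seen.

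Several genes of the contractile apparatus of smooth muscle and myofibroblasts fell with Irf1 siRNA. After the falls of Cnn1, Actg2, Acta2 and Csrp1 had been seen, 20 such genes were listed, of which 19 were tested, 15 fell and 0 rose (mean log2 fold change −0.78, SD 0.64). Acta2 went from 684.1 to 275.8 CPM, Myl9 from 71.2 to 32.2 CPM and Tagln from 281 to 156 CPM, and Mylk, Smtn, Tpm1 and Flna fell by 0.65, 0.58, 0.54 and 0.45 on the log2 scale. The mean stayed between −0.84 and −0.72 when single libraries were left out. Of the 10 members that hold no seed word, had not been seen and are not among the genes that fell further than Irf1, 7 fell (mean −0.43, SD 0.20; camera p = 1.0e-07, and 0.038 with an estimated correlation). The words searched therefore do not explain the fall of these 7 genes, although a gene upstream of them might hold one. Other words that went with falls, such as TCTGATC (z = −9.7) and TGCTATC (−9.0), were not searched in the members. A direct effect of the siRNA through such words stays open. Of other cell-type markers, 6 of 20 fibroblast markers fell and 1 rose, and 3 of 13 osteoblast markers fell and 0 rose. Of 10 endothelial and mural markers only Acta2, itself a contractile gene, fell, while Mcam rose by 0.86, and the muscle marker Des rose by 0.43.

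Of the 35 genes that fell further than Irf1, 27 hold a seed word in the 3′ UTR, and the rest, among them Cnn1 and Actg2, hold none there. Among genes with an annotated 3′ UTR and no call, 1963 of 9652 (20.3%) hold one. The words were chosen for going with falls in these same genes, and the shares are not adjusted for 3′ UTR length. They are therefore not a separate test of pairing of the siRNA with other transcripts. Across 16192 words of 7 bases and the 3′ UTRs of 10083 genes, the words that went with the lowest fold changes were CTGATCA (z = −16.7), GCTATCT (−16.2) and ACTGATC (−15.5). The next, TCTGATC, gave −9.7, and 100 permutations gave at most 4.9 in size. CTATCTA, also counted as a seed word, gave −8.0, behind TCTGATC and others. It was taken as a match of the same strand as GCTATCT. A single stretch of 19 bases in the Irf1 coding sequence, CAGATAGCACCACTGATCT, holds the match of 1 seed at each end of the duplex it would give: its summed z of −31.7 ranked first of 2051 windows, with −17.2 for the best window more than 3 bases away. The siRNA sequence is not given in the labels, so that this stretch is the target is a hypothesis from the same data. Bias from GC content or length is argued against for these genes by the size of the fall. The median log2 fold change was −1.27 after that correction against −1.30 before. All 35 of the 35 also stayed lower past the threshold, but genes picked for large falls were likely to keep their calls. After thinning 35 also stayed lower (median −1.32). The genes were picked for large falls and thinning keeps the expected fold change, so that result was nearly fixed in advance and does not judge depth. Genes that fell with such a word may therefore report the siRNA and not loss of IRF1, and an effect of IRF1 on them stays open.

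The repair and cell cycle lists were weighed against the same words and against fewer dividing cells. Without genes holding a word, the double-strand break repair list gave an adjusted p of 0.054 (0.034 when only genes with no annotated 3′ UTR were left out), and its mean went from −0.146 ± 0.026 (SE, 47 members) to −0.097 ± 0.030 (24 members), so that words may account for part of the fall and fewer members for part of the lost call. Its 20 members of S and G2 phase had a lower mean than the other 27, as fewer dividing cells would need (−0.21 against −0.10, SD 0.17 each, p = 0.033 in a permutation test over members). That p treats members that move together as independent, so this stays open. The split was not among the lists fixed before the data were examined. It also keeps the members holding a word, so words and division were not told apart. The cell cycle list kept its call without genes holding a word (camera adjusted p = 2.8e-07). This argues against the words searched in its members as the whole cause, but only at the preset correlation. An estimated correlation ended the call of the full list (0.70). Other words that went with falls, such as TCTGATC (z = −9.7), were not searched in the members. Whether division slowed was not measured, and the part of IRF1 stays open.

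The lower MHC class I list was weighed against both technical causes. It kept its call without genes holding a word (camera adjusted p = 0.00082) and after correction for GC content and length (0.00083). At the preset correlation this argues against the words searched, and against GC content and length, as the whole cause. An estimated correlation ended the call of the full list (0.70). Other words that went with falls were not searched in the members. A fall through IRF1 stays open and was not tested apart from the siRNA, and the interferon-gamma list lost its call in both settings. Its call also ended when only genes with no annotated 3′ UTR were left out (0.067), with every member kept, so its loss without genes holding a word (0.14; mean −0.22 against −0.40) cannot be put down to words alone. The mean stayed at −0.39 after the correction (0.077), so that loss does not point to GC content or length.

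The 10 splits of the 6 libraries into 3 and 3 cannot give a share under 0.05. The real split gave 3289 changed genes, 1522 higher and 1767 lower, with 0 as the highest other for each. That makes 1 of 10 splits for the changed, 1 for the higher and 1 for the lower genes. Every other split mixes both treatments on each side, so the treatment difference adds to the spread there. Its 0 calls were thus nearly fixed in advance, and no conclusion is drawn from them. The real split gave 9 lists past the threshold in camera, with 9 as the highest other, which makes 2 of 10. That other split was control replicates 1 and 2 with Irf1 siRNA replicate 3 against the rest. Every mixed split called at least 2 lists although it called 0 genes. Each mixed split still sets 2 libraries of 1 treatment and 1 of the other against the reverse. Part of the treatment difference therefore stays between its sides, and its list calls cannot show whether camera calls lists without one.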
